A study of Mus musculus with 4 samples.

How the data were processed

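The series profiled total RNA of mouse embryonic fibroblasts without p19ARF on Illumina bead arrays, 4 arrays in all, 2 for cells with a control vector and 2 for cells with wild-type NSD2. Per the labels' protocols, RNA was purified with a column kit, amplified and biotin-labelled with an Illumina amplification kit, and the cells grew in a serum-containing medium with no treatment. Groups and replicate numbers were taken from the sample titles. The series' design text speaks of triplicates, and 2 arrays per group were analysed here. The labels also carry entries for tissue and age that do not describe embryonic fibroblasts, and these were not used. Their entry for sex is set against the signals of sex-linked genes under other observations.

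The first deposited table, per the file headers, holds the average bead signal of each probe and array, an intensity on a linear scale that is neither normalized nor background-subtracted. It has 25697 probes and carries no detection p-values and no control probes. The second table holds the authors' processed values, also an intensity on a linear scale. How the authors made them is not given in the sources used here. Set against the same array's signal, each column kept the order of the probes (Spearman correlation across probes 1, probes not being independent replicates), with fitted slopes of 1.22, 0.823, 1.25 and 0.751 for control vector 1 and 2 and NSD2 1 and 2. Their medians were 48.7, 42.4, 48.6 and 42.3, and 1319, 765, 1470 and 225 values were negative. This comparison settles that the processed values are linear, not centred per gene, and run in the direction of the signal. Which normalization produced them stays unknown.

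Probe names came from the platform annotation supplied with the data. Of the probes, 23978 have 1 gene symbol, 0 have several and 1719 are unnamed here. Gene identifiers were looked up in a RefSeq gene table (GRCm38.p6), where those of 23962 probes were found and 0 symbols changed. That table was used for names only, and no coordinates are given because the files name no genome build. The named probes stand for 16593 genes, 4777 of them with several probes, and each gene is given by the probe with the highest mean, and for named genes an opposite sign of another probe above background on any array is stated.

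Before the data were examined, the plan was to normalize with neqc and to filter probes on detection p-values, falling back on normexp with an offset of 50 and quantile normalization on all probes if the table had no detection p-values. The fallback was used, with limma 3.58.1 in R 4.3.3. Because the offset compresses differences of dim probes, fold changes of genes near background are understated. Groups were compared with lmFit and eBayes, with no covariate, all 4 arrays and a two-sided test, and p-values were adjusted by Benjamini-Hochberg over all 25697 probes at a threshold of 0.05. Fold changes are log2 values of NSD2 minus control vector, given with their standard error from the moderated fit.

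In place of detection p-values, background was estimated on each array after the files had been inspected. The lower side of the signal distribution was mirrored about its mode, and a probe above the upper 5% point of this mirrored distribution was called above background. The thresholds were 185, 219, 178 and 182 for control vector 1 and 2 and NSD2 1 and 2, and 11182, 11235, 10865 and 11807 probes lay above them. On all 4 arrays 9779 probes (6902 genes) were above background, on at least 2 arrays 11424 probes (7872 genes), and on none 12396. Where a probe was above background on no array of a group, its fold is a bound. The brighter group's mean is then set against the mean, in the dim group, of the higher of the probe's own value and the lowest value among probes above background on that array.

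The genes named follow a rule fixed in advance. It takes Nsd2 (Whsc1), Nsd1, Tgfa, Met, Pak1, Rras2, Cdkn2a and Cdkn2b where measured, and up to 12 genes per direction past the threshold with detection on all 4 arrays and no overlap between the groups. It adds the leading members of each described list and up to 4 genes per direction detected in 1 group only. Detection was replaced by signal above background. Because only 4 genes passed, the largest other differences and list members below the threshold are named too, having been chosen after their values were seen. The 33 gene lists, fixed in advance, were tested with camera (preset correlation 0.01, and an estimated correlation) and fry.

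The procedure was tested on simulated data for this comparison, with 200 of 25697 probes changed in each of 5 runs. The fit of the groups alone found 7.40% of the 2-fold and 99.6% of the 4-fold changes with 0 false calls, and the fit with the replicate number found 92.2% and 100%, with 6.52% of its calls false. Changes were planted only in probes above background on all 4 arrays, so these rates do not cover dim probes. The spread was drawn from probes of like intensity, which evens out differences between probes. A difference between replicate numbers, shared by the groups, was built in, and the rates of the fit with the replicate number assume it. Alternatives covered the background correction, the offset, the scaling, the authors' processed values (log2 after adding 50), the variance moderation, the replicate number as a term, leaving out each array, the probe chosen for a gene, and filters on dim probes. Offsets of 1, 16 and 100, the filters on background, and combinations with the replicate number were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.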

Results

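Gene expression was measured on Illumina mouse bead arrays in fibroblasts from mouse embryos that lack p19ARF, a product of the Cdkn2a locus that restrains MDM2 and thereby stabilises p53. The cells carried either a control vector or wild-type NSD2, the methyltransferase that dimethylates histone H3 at H3K36, and each group held 2 arrays (n = 2). The series title concerns the link between this histone mark and an oncogenic expression programme, and the single contrast of the design asks which transcripts differ once NSD2 is added. The median signal over 25697 probes was 173 and 204 on the control arrays and 164 and 172 on the NSD2 arrays, and 42.3% to 45.9% of the probes on an array lay above its background. The 75th percentile of the signal was 357 (control vector 1) and 345 (NSD2 1), against 490 (control vector 2) and 491 (NSD2 2), so that brightness followed the replicate number and not the group. The number of arrays limits the precision of every value, and nothing in the labels says whether the replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

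In the cells with NSD2, 4 genes rose and 0 fell among 16593 genes (limma, Benjamini-Hochberg adjusted p under 0.05). Gpc3, which encodes the cell-surface heparan sulphate proteoglycan glypican-3, rose from a log2 intensity of 6.78 ± 0.01 to 8.71 ± 0.30 (mean ± SD, n = 2 per group), a log2 fold change of 1.94 ± 0.21 (SE, limma adjusted p = 0.0030). Hoxd8, a homeodomain transcription factor of the Hoxd cluster, rose from 7.11 ± 0.35 to 9.03 ± 0.36, a 3.80-fold difference (log2 fold change 1.93 ± 0.24, limma adjusted p = 0.0054). Mest, an imprinted gene expressed from the paternal allele, rose 3.18-fold, from 8.25 ± 0.05 to 9.91 ± 0.24 (log2 fold change 1.67 ± 0.21, limma adjusted p = 0.0054). Prr15, which encodes a small proline-rich protein, rose 2.75-fold, from 7.94 ± 0.38 to 9.40 ± 0.13 (log2 fold change 1.46 ± 0.22, limma adjusted p = 0.049). Each of the 4 genes was higher on both NSD2 arrays than on either control array. The probe used for Gpc3 was above background on neither control array, so the rise at this probe is given as at least 3.31-fold, while that for Hoxd8 was above background on 3 arrays. Another Gpc3 probe differed by a log2 value of 1.21 (limma adjusted p = 0.072), which is less than that bound. The other probes of Mest differed by 1.43 (limma adjusted p = 0.054) and by 0.34, the latter above background on 1 array. Groups of 2 against 2 allow 3 splits, so an exact test of 1 gene cannot reach a two-sided p below 0.333, and the calls rest on the spread that limma shares between genes. The groups did not overlap in 5304 genes (32.0%). Chance gives 33.3% only if all 4 arrays vary independently. Same-numbered arrays varied together here, so this comparison decides nothing. The count of 4 became 11 without control vector 1 and 12 without control vector 2 (Prr15 missed the threshold without control vector 1 and without NSD2 2), 10 with a robust trended variance, and 37 with the replicate number as a term in the fit. It became 0 with median scaling, with the authors' processed values, with an offset of 1 or 16, or over probes above background on all 4 arrays, and 1 (Gpc3) over probes above background on at least 2. Tests below are those of the fit of the groups alone unless another is named.

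**Figure D1:**
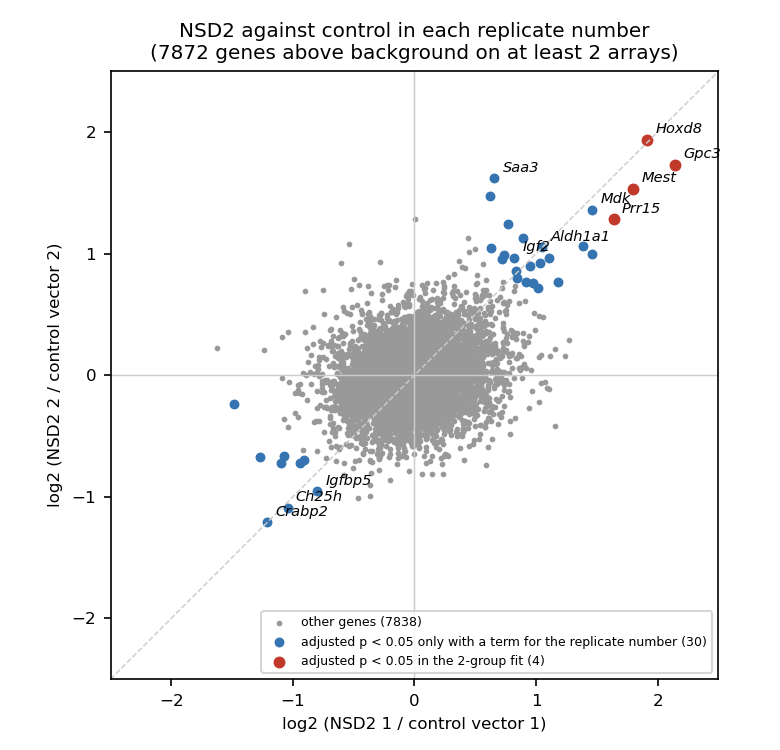
Each point is a gene above background on at least 2 arrays (7872 genes), with the log2 ratio of NSD2 1 to control vector 1 on the x axis and of NSD2 2 to control vector 2 on the y axis. Red points are the 4 genes with an adjusted p under 0.05 in the fit of the groups alone, blue points 30 further genes that pass it once the replicate number is a term in the fit, and grey points the other 7838 genes. Gpc3, Hoxd8, Mest and Prr15 lie far up and right of the cloud, at ratios of 1.29 to 2.14.

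The genes named next are a selection from the largest differences below the threshold, made after their values were seen. None of them passed the test over all genes in the fit of the groups alone. Mdk, which encodes the heparin-binding growth factor midkine, had a log2 intensity of 8.69 ± 0.38 in control cells and 10.11 ± 0.45 with NSD2 (log2 fold change 1.41 ± 0.25, limma adjusted p = 0.10), and another Mdk probe differed by 1.22. The retinaldehyde dehydrogenase gene Aldh1a1 differed by 1.05 ± 0.20 (adjusted p = 0.18), with differences of 1.05 in both replicate numbers. Crabp2, which encodes a cellular retinoic acid binding protein, differed by -1.21 ± 0.20 (adjusted p = 0.072), and by -1.21 in both replicate numbers. Igf2, the imprinted insulin-like growth factor gene, stood at 13.65 ± 0.09 in control cells and 14.54 ± 0.19 with NSD2 (0.89 ± 0.21). Its binding protein genes differed in opposite directions, Igfbp2 by 1.01 ± 0.26 and Igfbp5 by -0.88 ± 0.24. Trf, which encodes the iron carrier transferrin, differed by 0.84 ± 0.21, and the tight junction gene Cldn15 by 1.22 ± 0.22. Ch25h, which encodes cholesterol 25-hydroxylase, differed by -1.07 ± 0.31. Regardless of p, the measured means of 13 genes were at least 2-fold higher and of 2 at least 2-fold lower with NSD2. For replicate 2 against replicate 1 the same counts were 12 and 5, so a difference unrelated to the groups reached a like size. For the third split, control vector 1 and NSD2 2 against control vector 2 and NSD2 1, both counts were 0. The 13 include Kcnk1, above background on neither control array, whose difference is known only as at least 1.49-fold. In all, 649 of 16593 genes had an unadjusted limma p under 0.05, which is below a share of 0.05. This fit counts the difference between replicate numbers as spread, so that share is not its chance level and the comparison decides nothing. The same count was 375 for the third split, 1631 for replicate 2 against replicate 1, and 1301 for NSD2 with the replicate number as a term.

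**Figure D2:**
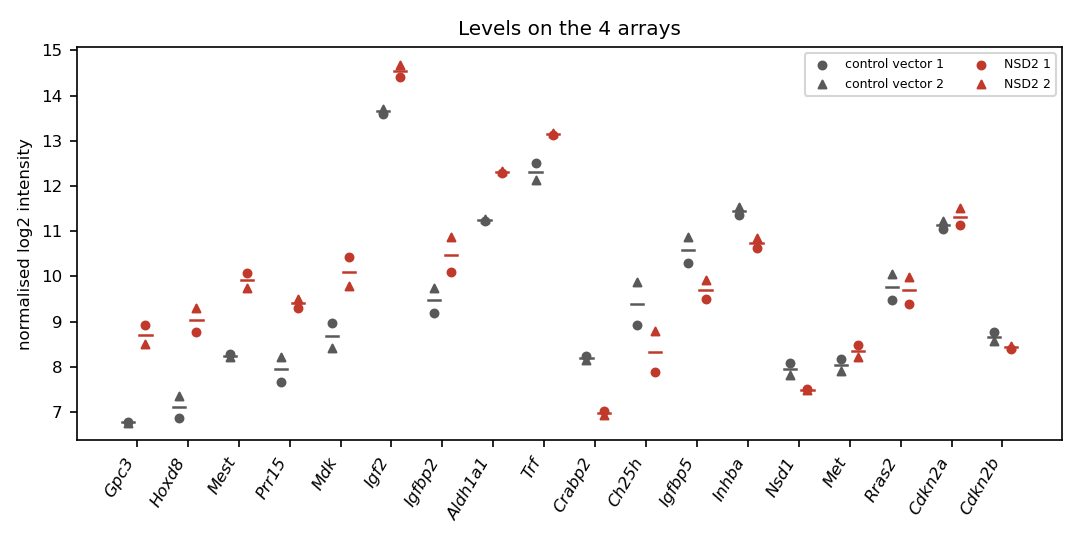
Normalised log2 intensity (y axis) of 18 genes (x axis) on the 4 arrays, with control vector arrays in grey and NSD2 arrays in red, circles for replicate 1, triangles for replicate 2, and a bar at each group mean. Gpc3 and Mest separate clearly by group (6.78 against 8.71 and 8.25 against 9.91), whereas the Rras2 arrays separate by replicate number (means of 9.77 and 9.69 in the 2 groups).

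Growth signalling genes linked to NSD2 in myeloma were followed irrespective of their size of change. Met, the receptor of hepatocyte growth factor, stood at 8.04 ± 0.18 in control cells and 8.35 ± 0.20 with NSD2 (log2 fold change 0.31 ± 0.21), and the small GTPase gene Rras2 at 9.77 ± 0.39 and 9.69 ± 0.41 (-0.08 ± 0.25). Tgfa, which encodes a ligand of the epidermal growth factor receptor, was above background on 0 arrays, and its level was not measurable here. Nsd1, a related H3K36 methyltransferase gene, stood at 7.95 ± 0.18 in control cells and 7.50 ± 0.03 with NSD2 (-0.45 ± 0.21, limma adjusted p = 0.9996), while another Nsd1 probe, above background on 0 arrays, differed by -0.02. At the INK4 locus, Cdkn2b differed by -0.23 ± 0.20 and Cdkn2a, at 11.14 ± 0.12 and 11.31 ± 0.27, by 0.17 ± 0.21 (another Cdkn2a probe, below background, by -0.33). The Cdkn2a probe may lie outside the deleted part of the locus, so its signal checks nothing about the p19ARF deletion. Adjusted p was 0.9996 for each of these genes. No named probe was matched to the transduced gene itself, Nsd2 (Whsc1), or to Pak1, and neither was analysed here.

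Values adjusted over a list alone were not adjusted across the lists, so such passes are weak. Among the 33 gene lists fixed before the data were examined, the list of growth factors and receptor kinases had the most members that passed when adjusted over the list alone, 5, against 0 over all genes. These were Igfbp2, Igfbp5, Igfbp3 (0.67 ± 0.20), Gas6, the ligand of the receptor AXL (0.78 ± 0.24), and the lymphatic growth factor gene Vegfd (0.65 ± 0.21). Of its 24 members above background, 14 had higher and 10 lower means with NSD2. Among TGF-beta and BMP targets, 7 of 16 members were higher, and 2 passed adjusted over the list alone against 0 over all genes: the BMP antagonist gene Grem1 (0.84 ± 0.24) and the activin subunit gene Inhba (-0.70 ± 0.21). Of the NF-kB and inflammatory genes, 13 of 22 were higher, and the acute-phase gene Saa3 (1.14 ± 0.29) passed adjusted over the list alone but not over all genes. The neutrophil chemokine genes Cxcl5 and Cxcl1 had values of 0.63 ± 0.20 and 0.54 ± 0.24. In the Wnt list 10 of 14 members had higher means, among them the feedback regulator Axin2 (0.48 ± 0.22) and the ligand Wnt5a (0.65 ± 0.21, with -0.18 for another Wnt5a probe). MAPK feedback genes were split evenly, 10 higher and 10 lower, with Fos at 0.65 ± 0.33 and Fosl1 at -0.45 ± 0.21. No member of the Wnt or MAPK list passed, adjusted over the list alone or over all genes.

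The imprinted list held 1 gene that rose over all genes tested, Mest, and 2 when adjusted over the list alone, Mest and Igf2. Further members were Grb10, an adaptor of insulin and growth factor receptors (0.55 ± 0.24), Dcn, a matrix proteoglycan gene (0.51 ± 0.20), and Ndn (-0.29 ± 0.20), and 8 of 14 members above background had higher means. Of the 11 Hox genes above background, only Hoxd8 passed, over all genes and over the list alone. Of the other Hoxd genes, the probes of Hoxd4 (at least 1.04-fold higher) and Hoxd11 (at least 1.08-fold) were above background on the NSD2 arrays only. Those of Hoxd1, Hoxd3, Hoxd9 and Hoxd10 were above background on 0 arrays, with differences of -0.11, 0.22, -0.04 and 0.23, so no shared rise of the cluster was shown. Hoxa7 stood at -0.42 ± 0.22. EMT and mesenchymal regulators had lower means in 13 of 16 members, among them Meox1 (-0.65 ± 0.22) and Prrx1 (-0.38 ± 0.23), both homeobox genes. Enzymes of H3K36 and H3K27 methylation were split between 7 higher and 8 lower means, and the demethylase gene Kdm6b stood at -0.44 ± 0.21. No member of the last 2 lists passed, adjusted over the list alone or over all genes. No list passed the competitive camera test. The smallest adjusted p was 0.442, shared by the imprinted, Wnt, EMT, NRF2 and growth factor lists, and 0.964 with an estimated correlation. The smallest unadjusted p was 0.040, for the imprinted list. The self-contained fry test gave a smallest adjusted p of 0.348. In 5 lists (Hox, imprinted, skeletal muscle, bone and cartilage, ER stress) the median, the mean and the direction of the camera test did not share 1 sign.

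Matrix and cytoskeletal genes, the main products of fibroblasts, had 0 members past the threshold, adjusted over each list alone or over all genes. Among collagen and matrix genes 18 of 33 had higher means, including elastin (Eln, 0.62 ± 0.23) and Col6a1 (0.44 ± 0.20), and thrombospondin 2 (Thbs2) stood at -0.42 ± 0.22. Matrix proteases and their inhibitors were higher in 7 of 19, with Adam12 at 0.49 ± 0.25 and Mmp14 at -0.39 ± 0.21. Contractile and SRF target genes were higher in 9 of 19, with Ankrd1 at -0.47 ± 0.23 and Tagln at 0.25 ± 0.20.

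Genes of the cell cycle and of growth likewise had 0 members past the threshold, adjusted over each list alone or over all genes. DNA replication genes had lower means in 18 of 29 members, with Pold1, a DNA polymerase subunit gene, at -0.36 ± 0.20, and mitotic genes higher means in 14 of 22, with Ube2c at 0.32 ± 0.25 and Plk1 at -0.33 ± 0.21. Of the p53 targets 8 of 19 were higher, and Cdkn1a, the p21 gene, stood at -0.23 ± 0.22 (other probes at 0.04 and -0.21). Senescence and INK4 genes were higher in 4 of 10, with Lmnb1 at 0.35 ± 0.21. MYC and ribosome biogenesis genes were higher in 9 of 23, with Ppan at 0.58 ± 0.22 and Bop1 at -0.42 ± 0.23.

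Metabolic and stress genes gave the same counts of 0, over each list alone and over all genes. NRF2 targets had lower means in 12 of 15 members, among them Txnrd1 (-0.33 ± 0.22), while the glutathione transferase gene Gsta4 stood at 0.61 ± 0.21. Cholesterol synthesis genes were higher in 10 of 16, with Msmo1 at 0.39 ± 0.23. Glycolysis and hypoxia genes were higher in 9 of 21, with Pfkp at -0.46 ± 0.21. ER stress and amino acid response genes were higher in 14 of 26, with the chaperone gene Hspa5 at 0.46 ± 0.25 and Trib3 at -0.37 ± 0.25. Heat shock genes were higher in 6 of 14, with Ahsa1 at -0.53 ± 0.20, and interferon-stimulated genes in 6 of 14, with Irf9 at 0.42 ± 0.21 (another probe at -0.13).

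Markers of other cell types were mostly below background. Of the haematopoietic markers 1 of 15 was above it (Cd14, -0.18 ± 0.22), of the endothelial markers 4 of 16, of the neural and glial markers 5 of 17 and of the epithelial markers 6 of 15. Flt1, an endothelial VEGF receptor gene, stood at -0.65 ± 0.21, Gap43 at 0.37 ± 0.21 and Krt19 at -0.41 ± 0.21. Of the adipocyte genes 8 of 22 were above background, with Lpl, the lipoprotein lipase gene, at 0.58 ± 0.21. Of the bone and cartilage genes 7 of 23 were, and 6 of these had higher means, with Omd at 0.45 ± 0.21. Of the skeletal muscle genes 5 of 24 were. Adjusted over the muscle list alone 2 passed, Des, which encodes the intermediate filament desmin (0.86 ± 0.23), and Ckm, which was above background on 0 arrays. No member of these 7 lists passed over all genes, and in the other 6 none passed over the list alone. Reference genes lay between -0.15 and 0.24, with Actb at 0.02 ± 0.25 and Gapdh at 0.01 ± 0.21, and 3 of 4 measured sex-linked genes were above background, with values of 0.04 to 0.32.

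**Figure D3:**
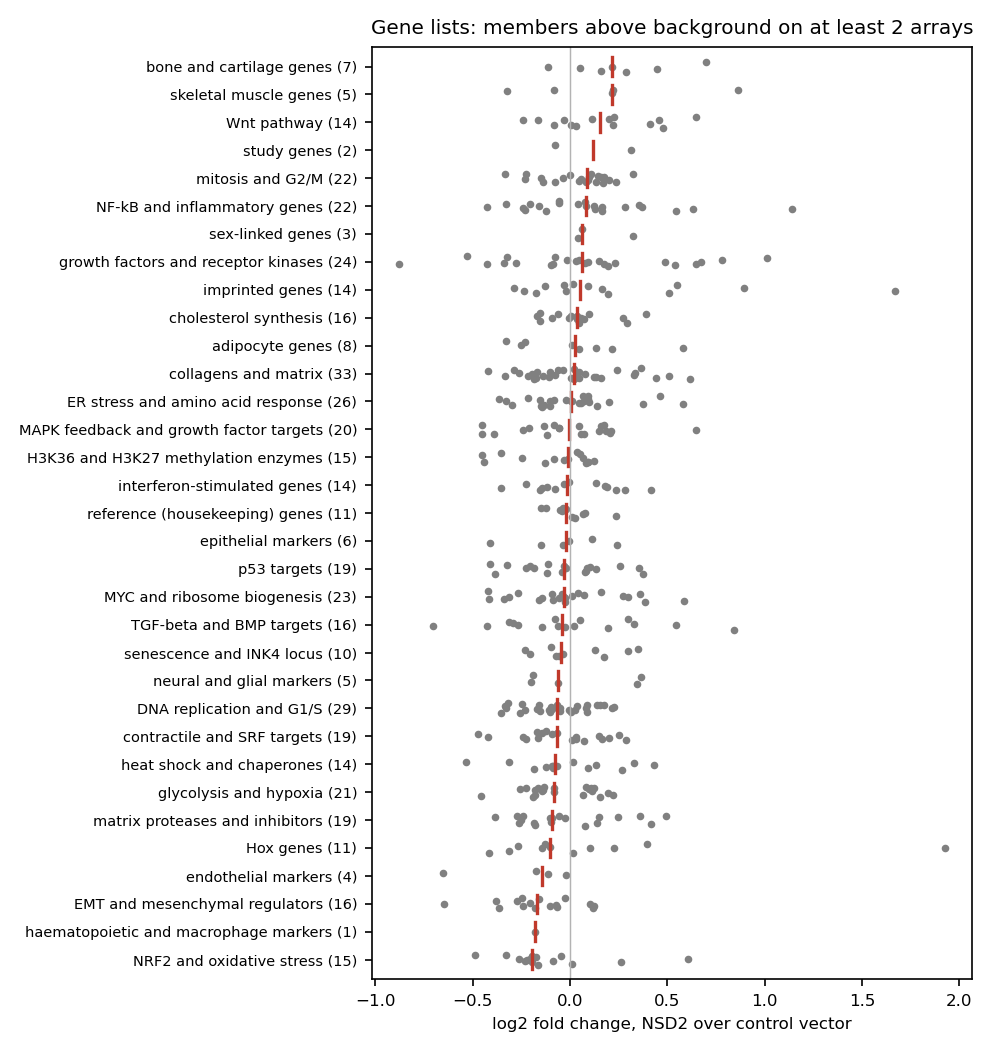
Log2 fold change of NSD2 over control vector (x axis) for the members of the 33 gene lists (y axis, with the number of members above background on at least 2 arrays), one grey point per gene and a red bar at each list's median. Over all measured members the medians of 28 of the 33 lists lay within 0.1 of 0, and Hoxd8 (1.93) and Mest (1.67) stand apart from the rest of their lists.

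Some probes were above background on both arrays of 1 group and on neither of the other. Besides that of Gpc3, those with the largest bounds higher with NSD2 were of the potassium channel gene Kcnk1 (at least 1.49-fold), the zinc finger gene Zfp566 (at least 1.45-fold) and the cartilage collagen gene Col2a1 (at least 1.43-fold). In the other direction they were of the transcription factor gene Tfap2b (at least 1.38-fold lower), the quinone reductase gene Nqo1 (at least 1.34-fold), the kinase gene Bmx (at least 1.30-fold) and Fbxl2 (at least 1.25-fold). Of these probes only that of Gpc3 passed the test over all genes in the fit of the groups alone. Gpc3 and Col2a1 each have another probe that was above background on 3 arrays, the Col2a1 one differing by 0.21, and the other Bmx probes, below background, differed by 0.18 to 0.31.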

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

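The neqc normalization, its offsets and detection filters could not be run without detection p-values. The offsets, background filters and combined settings below were chosen after seeing the data. Directions of the 4 genes that rose held throughout, and their calls did not. Gpc3, with only a bound, was called in 16 of 21 alternatives, Hoxd8 (log2 fold change 1.54 to 2.43) in 15 of 21, Mest (1.48 to 1.85) in 15 of 22, and Prr15 (1.19 to 1.73) in 12 of 22, with adjusted p reaching 0.9996 (0.9998 for Prr15). Leaving out 1 array gave 5 to 12 genes changed by NSD2, and 5 to 12 changed at least 2-fold. The lone array of a group is then assumed to vary like the other group.

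The count of 4 genes changed by NSD2, all at least 2-fold, stayed within 1.5 times (3 to 5 genes) with no background correction, cyclic loess, an offset of 100, all probes counted, or the probe with the largest variance. It fell to 0 (0 at least 2-fold) in these limma fits: median scaling (smallest adjusted p = 0.111, 210 genes at an unadjusted p under 0.05), the authors' processed values (0.0597, 618 genes), an offset of 1 (0.9996, 692 genes), an offset of 16 (0.680, 677 genes) and probes above background on all 4 arrays (0.0989, 236 genes). Probes above background on at least 2 arrays gave 1 (1 at least 2-fold), and robust trended moderation 10, of which 9 rose (9 at least 2-fold). The cause was not tested. Of all probes, 12396 were above background on no array.

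The replicate numbers are shared by the groups, but the labels name no shared batch and there are only 2 pairs, so no pairing is established. Deviations of same-numbered arrays from their group means correlated at 0.521 across 6902 genes, which are not independent replicates. With the replicate block 37 genes were called, 27 higher and 10 lower (15 at least 2-fold), on 1 residual degree of freedom per gene. The spread shared between genes counted for 84.7 degrees of freedom in this fit. Of the 37 genes, 34 were above background on at least 2 arrays. Among the 37 were Mdk, Aldh1a1, Crabp2, Igf2, Igfbp2, Igfbp5, Trf, Cldn15, Ch25h, Saa3, Grem1, Des, Kcnk1 and Bmx. The block gave 106 genes (15 at least 2-fold) over probes above background on at least 2 arrays, 13 (12) with cyclic loess, 27 (15) with median scaling, 122 (8) without background correction, 127 (15) with robust trended moderation, and 0 (0) on the authors' processed values (limma, smallest adjusted p = 0.0717, 935 genes at an unadjusted p under 0.05). Camera with the block over probes above background passed the imprinted list (mean 0.23, adjusted p = 0.0086). EMT (-0.16, 0.046) and bone and cartilage (0.25, 0.046) passed too. With the block and no background correction, imprinted genes did (0.14, 0.011). A correlation estimated on 1 residual degree of freedom gave adjusted p = 0.949 and 0.850 in these settings, deciding nothing. Of the other values, 5613 for named genes and 752 for lists stayed on their side of the threshold, 245 for named genes gained a call, the 28 losses were all of the 4 genes above, and 0 reversed (sign changes between values that passed in neither setting not counted). The mean of 8 lists changed sign under a scaling or background alternative, and the median over all genes lay at most 0.016 from 0.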

Other observations

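The tests on the folds of the genes called with the replicate number as a term were chosen after those folds had been seen, as were the genes named here, whereas those on the difference between replicate numbers were set beforehand. Beyond the genes described so far, the differences called in that fit include those of the next 3 sentences, none of which passed in the fit of the groups alone. The leukotriene receptor gene Cysltr1 differed by 1.23 ± 0.21 and the adaptor gene Tril, of the innate immune receptors, by 0.97 ± 0.28. The sialyltransferase gene St3gal6 differed by 0.98 ± 0.21. On the lower side stood Cacna2d1, a calcium channel subunit gene (-0.91 ± 0.24), Rnf144a, a ubiquitin ligase gene (-0.98 ± 0.23), and Prf1, the perforin gene (-0.87 ± 0.23). Igf2bp3, which encodes an RNA-binding protein named for Igf2 mRNA, stood at -0.74 ± 0.22 (another probe at -0.24) and Hey1, a Notch target gene, at -0.70 ± 0.24, neither called in either fit.

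The labels give the cells' sex as female, which the following signals of Y-linked genes and of Xist go against. Eif2s3y, a gene of the Y chromosome, had signals of 1292, 1622, 1209 and 2676 on control vector 1 and 2 and NSD2 1 and 2, above background on all 4 arrays, and Kdm5d, also of the Y chromosome, was above background on 4 arrays and Uty on 3. Both Xist probes were above background on 0 arrays. The X-linked relative of Eif2s3y, Eif2s3x, had signals of 1218, 2115, 1485 and 2958.

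Arrays of different replicate number differed more than arrays of different group. Over 6902 genes the SD of the log2 difference was 0.31 between the control arrays and 0.33 between the NSD2 arrays, against 0.27 and 0.24 between the groups within replicate 1 and 2, and 6 genes passed between the replicate numbers, led by Exosc2 (2.28 ± 0.22, with -0.43 for another Exosc2 probe) and Ric8b (1.45 ± 0.21, with 0.76 for another Ric8b probe). Among 28 genes with another probe and a difference of at least 0.7, that other probe showed a median of 0.211 of the brighter probe's difference (95% bootstrap interval 0.033 to 0.372), with the same sign in 21 genes. A low share would be seen with a difference at the level of single probes, such as hybridisation or array handling. However, the genes were picked by the brighter probe's own difference, which biases the share downwards. A difference in the RNA of the cultures stays open, since the interval reaches above the share of 0.25 set to exclude it.

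Whether the 37 genes called with the replicate number as a term respond to NSD2 was decided by no test here. Scaling or background correction as the cause of these folds stays open. The genes were picked for large folds in the same signals, so a loss of sign or of most of the fold was unlikely beforehand. Offsets below 50 were not run with the replicate number as a term. Without background correction, with cyclic loess, with median scaling and on the authors' processed values, 0 of 37 genes changed sign. In these settings 0 of 37 fell below a share of 0.5 of their fold, and 36, 13, 27 and 0 of them were still called. Their median absolute log2 fold change was 0.94, against 0.82, 0.91, 0.91 and 1.03 in those settings. A misreading by single probes stays open, since the lower ends of both intervals given next lie below a share of 0.5. Among the 9 genes with another probe above background, that probe showed a median of 0.622 of the change (95% bootstrap interval 0.029 to 0.860), with the same sign in 8, and among 7 genes with a group difference of at least 0.7 the share was 0.820 (0.324 to 0.923), with the same sign in 7.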
